A study of Mus musculus with 23 samples.

How the data were processed

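Total RNA from 8 subclones of Lewis lung carcinoma (LLC), a transplantable mouse lung tumour cell line, was measured on 23 Affymetrix arrays with 45101 probe sets. Per the labels, the subclones came from the parental line by limiting dilution, grew in medium with 10% serum, and spent 24 h in a serum-free medium before RNA was taken. That last step is how conditioned medium is prepared. RNA was extracted with Trizol and purified on columns, and biotin-labelled cRNA was made by the manufacturer's routine protocol, per the labels. Each subclone had 3 arrays, except subclone 6 with 2, and the labels call the arrays of a subclone biological replicates. The labels name no parental sample, no reference subclone and no grouping of the subclones, so none was used.

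The deposited values are linear intensities, from 0.61 to 17068.52, with 1 value per probe set and array. The algorithm and scaling that the authors used to make these intensities are not given in the sources used here, and no detection calls were used here. The value 1 occurred 15024 times. Array medians lay between 40.83 and 45.74 and array means between 412 and 441.1. The 5th percentile lay between 2.08 and 2.39 on arrays of subclones 19, 23 and 24 and between 2.45 and 2.76 on the others. The labels give no dates or batches. No pair of arrays held identical values. For arrays, their number limits the precision.

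Values were taken as log2(intensity + 16), so a fold stated here is on that scale and understates the change of genes with low intensities. The pseudocount had been set in advance for the case of a linear table. Control probe sets (64) were left out. In the probe annotation used, 34958 probe sets had 1 gene symbol and 932 had several. It did not list 9160 other probe sets, which stayed unnamed and untested. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6 for 34754 probe sets. The sources name no genome build, so the table served for names, chromosomes and gene order, and no coordinates are given. Genes with over 1 probe set (9012) were represented by the one with the highest mean over all arrays, which left 18194 genes. No filter on low values was applied.

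One linear model with a coefficient per subclone was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 15 residual degrees of freedom). A moderated F-test asked whether the 8 means were equal. A contrast for each subclone compared it with the equally weighted mean of the other 7. These contrasts share arrays and are not independent of one another. A gene was called apart in a subclone at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. It was called private to that subclone if, in addition, every array of the subclone lay beyond every other array and the mean lay at least 1 log2 unit beyond the nearest other subclone. The same thresholds were applied to all 28 pairs of subclones. Similarity of replicates was measured by the root mean square log2 distance between arrays, with a one-sided permutation test of the subclone labels (100000 resamples).

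There were 25 gene lists, fixed before the data were examined. They covered secreted factors with reported effects on adipocytes or in cachexia, cytokines and chemokines, growth factors, extracellular proteases and their inhibitors, collagens and matrix proteins, epithelial genes, mesenchymal genes, interferon-stimulated genes, antigen presentation by MHC class I, proliferation, hypoxia with glycolysis, sterol and fatty acid synthesis, stress of the endoplasmic reticulum with the amino acid response, p53 targets, NRF2 targets, ERK pathway output, targets of Wnt, Notch and Hedgehog, targets of TGF-beta and YAP, leukocyte markers, markers of endothelium, fibroblasts and adipocytes, lung epithelial genes, Y-chromosome genes, cytosolic ribosomal proteins, oxidative phosphorylation, and surface receptors of tumour cells. Each was tested in each contrast with camera at its preset correlation of 0.01, adjusted over all 200 combinations. List members were counted as higher or lower at an adjusted p under 0.05, with no minimum difference. For subclone 23, the lists were also tested without members on chromosome 1, after the shift of that chromosome had been seen. The estimated correlation and fry's directional test were alternatives. Over-representation among genes with a range over 4-fold was tested with Fisher's exact test (two-sided), with all genes tested as background. Some list members had no probe set with a single symbol in the annotation and were not analysed here.

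The genes named in the text follow a rule fixed before the data were examined. It takes 1 secreted factor chosen in advance for every subclone, which is not analysed here, members of the adipocyte and cachexia list past the F-test with a range of at least 1 log2 unit, and the 25 genes with the largest range of subclone means. It also takes up to 6 private genes per direction in each contrast, ranked by difference, and up to 4 members of each called list. Where fewer than 3 genes were private in a direction, genes apart in that subclone with all its arrays beyond all others were taken instead. Clone and gene-model names were counted but not named.

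Simulated data with the real overall mean and spread of each gene tested the procedure on all 18194 genes. In them the other subclones did not differ and genes varied independently, so they were easier than the real data. In simulations of subclone 2 and of subclone 6, 100% of genes changed by 1.5 or by 2.5 log2 units were recovered with the right sign, and 0 unchanged genes were called apart, while 12 and 16 unchanged genes passed the F-test. The alternatives tried were quantile normalization, median centring, a filter at the 40th percentile of mean level, the mean of all probe sets of a gene, an intensity trend with a robust prior, array weights and the replicate number as a block. Pseudocounts of 1 and 64, other thresholds, another spread model and the omission of each array in turn completed them.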

Results

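The data compared 8 subclones of the mouse LLC line, each derived from the parental culture by limiting dilution and held without serum for 24 h, the condition in which conditioned medium is made. The arrays therefore recorded how far subclones of a single tumour line differ in expression, including in the genes for secreted proteins. Subclones 2, 3, 18, 19, 23, 24 and 28 had 3 arrays each and subclone 6 had 2. Levels below are means of log2(intensity + 16) ± SD over these arrays, and log2 differences from the mean of the other 7 subclones carry their standard error (SE) from limma. Members of gene lists were counted as higher or lower by adjusted p alone, whatever the size of the difference. Of 18194 genes, 6541, 6909, 4348, 7832, 7620, 6843, 5865 and 6798 passed that bar in subclones 2, 3, 6, 18, 19, 23, 24 and 28.

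The subclones differed over much of the transcriptome. Of 18194 genes tested, 11243 (61.8%) passed the F-test, 2308 of them had a range of subclone means over 2-fold, 454 over 4-fold and 57 over 16-fold. The median residual SD was 0.113 log2 units. Several of the widest ranges came from genes that were high in some subclones and near the floor in others. Bgn, the matrix proteoglycan biglycan, lay between 12.38 and 12.76 in 6 subclones, at 5.59 in subclone 18 and at 4.85 in subclone 19, a range of 240-fold. Armcx2, Col4a5 (a chain of basement membrane collagen) and Tmem47 were low in the same pair, at 4.69 or less against 8.98 or more elsewhere. Xist, the RNA that coats an inactive X chromosome, was at 11.38 in subclone 18, 11.34 in subclone 19 and 11.18 in subclone 28, and at 5.82 or less in the others. Efemp1, a matrix glycoprotein, was low in subclones 19 (4.72) and 28 (4.69) and at 11.18 or more elsewhere. Crabp1, a retinoic acid binding protein, was low in subclones 19, 23 and 28 (5.48 to 6.88) and at 10.75 or more in the remaining 5. Cthrc1 was at 4.51 or less in subclones 18, 19 and 28 and at 8.19 or more in the others. Scara5 and Itih5 were at 5.98 or less in subclones 18, 19 and 23, and Basp1 was at 7.58 or less there. Cd34, a surface sialomucin, and Dppa4, a gene of pluripotent cells, were higher in subclones 18, 19, 23 and 28 (8.84 or more and 7.29 or more) than in the other 4.

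**Figure D1:**
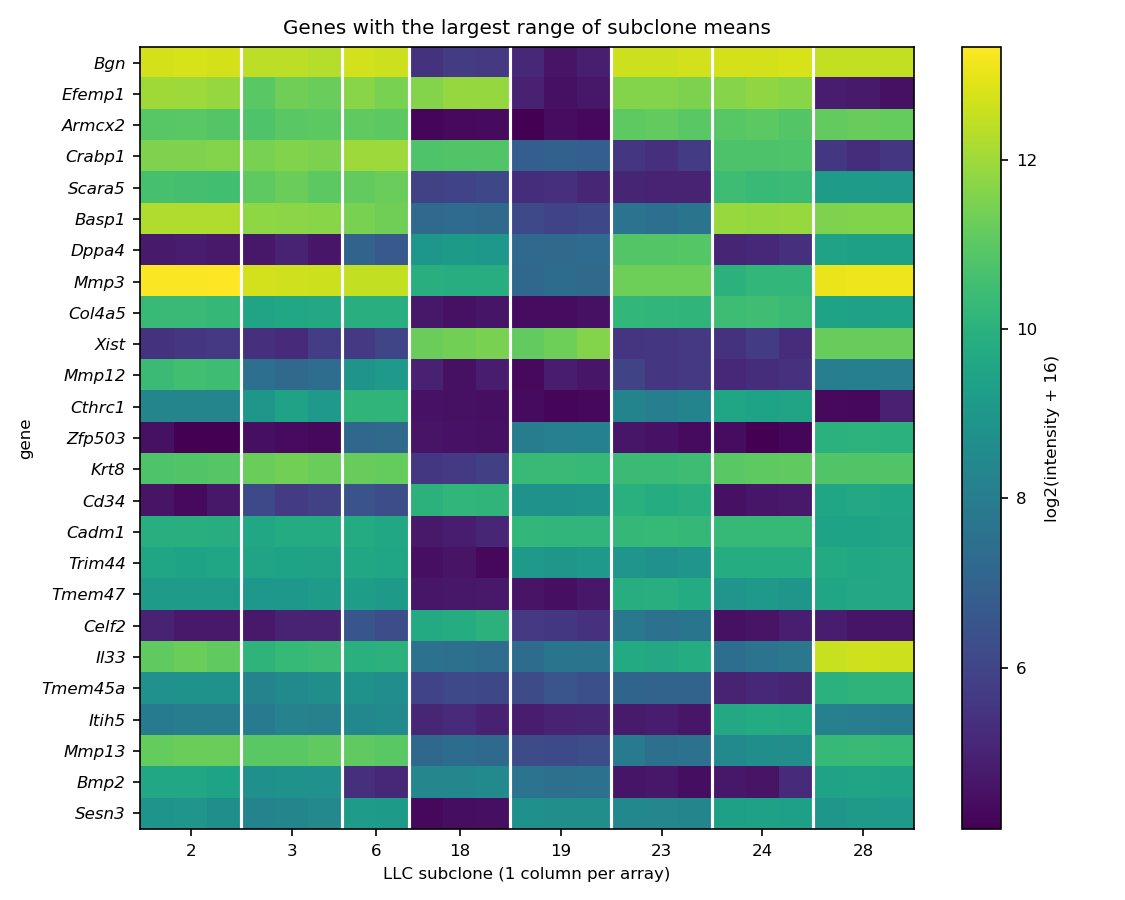
Heat map of log2(intensity + 16) for the 25 genes with the largest range of subclone means, with 1 column per array grouped by LLC subclone. Bgn is at 4.85 to 5.59 in subclones 18 and 19 and at 12.38 or more in the others, and replicate arrays of a subclone show closely similar colours.

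Arrays of one subclone lay closer to each other than to arrays of other subclones. The mean root mean square distance was 0.208 log2 units over 22 pairs within subclones (0.179 to 0.242) and 0.435 over 231 pairs between them (0.291 to 0.547), a ratio of 0.479. The permutation p was 1e-05, the smallest that 100000 resamples can give. Between pairs of subclones, the number of differing genes ran from 101 (subclones 3 and 6) to 819 (subclones 2 and 18), with a median of 454.5. Subclones 2, 3, 6 and 24 differed from one another by 101 to 327 genes. Subclone 28 was as close to subclones 2, 3 and 6 (275, 234 and 213 genes) as subclone 24 was (278, 327 and 198), but differed from subclone 24 by 514. Subclone 18 differed from each other subclone by at least 458 genes, and subclone 19 by at least 422. Subclone 6 has 2 arrays, so its comparisons are the least precise.

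**Figure D2:**
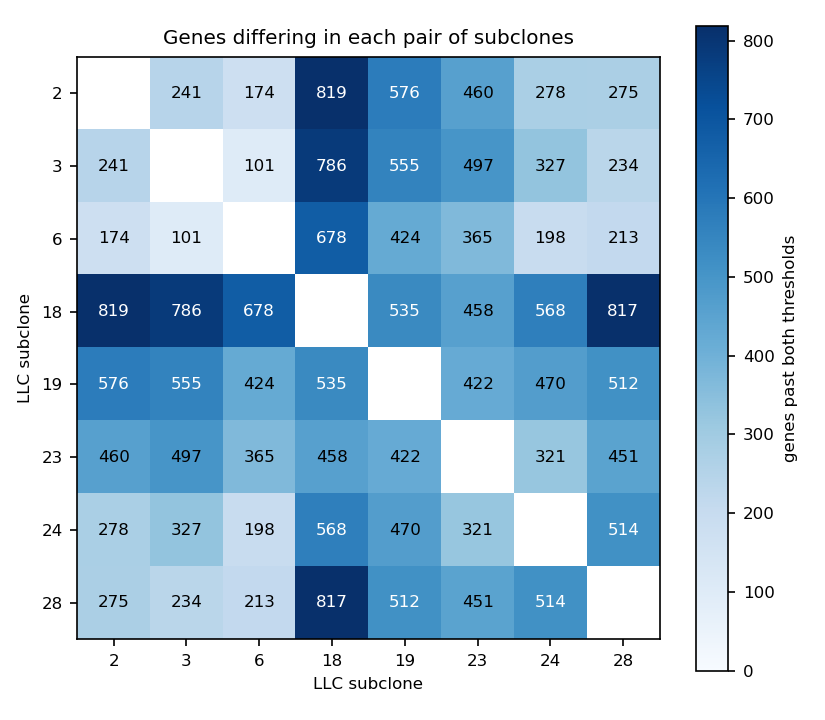
Number of genes past both thresholds (adjusted p under 0.05 and at least 1 log2 unit) in each of the 28 pairs of LLC subclones, shown as colour and as a number in each cell. Subclones 3 and 6 differ by 101 genes and subclones 2 and 18 by 819.

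Among secreted factors with reported effects on adipocytes or in cachexia, 37 of 44 listed genes were measured, and 19 passed the F-test, 19 also when adjusted over the list alone. Of the 37 measured, 8 (21.6%) had a range over 4-fold, against 2.5% of all genes tested (odds ratio 10.9, Fisher's exact test, adjusted p = 1.44e-05). The cytokine gene Il33 ranged from 7.5 in subclone 18 to 12.62 in subclone 28 and Bmp2, a bone morphogenetic protein, from 4.59 in subclone 23 to 9.55 in subclone 2. Lif and Il6, 2 cytokines that signal through gp130, were highest in subclone 28 (9.77 and 6.28) and lowest in subclone 24 (6.72 and 4.65). Outside subclone 28, single arrays of Il6 lay between 4.42 and 5.41, around the level of the filter on low values (5.3). The lowest rank of Il6 is therefore among values near the floor. Il11, of the same family, was between 8.64 and 9.59 in subclones 2, 3, 6 and 28 and between 6.50 and 7.95 in the other 4. Angptl4, an inhibitor of lipoprotein lipase, was highest in subclones 18 (11.05) and 23 (10.83) and lowest in subclone 6 (7.48). Slit2, an axon guidance ligand, was at 8.89 in subclone 23 and 4.72 in subclone 24. Inhbb, an activin and inhibin subunit, was at 8.26 in subclone 18 and 5.21 in subclone 23, whereas the related Inhba was lowest in subclone 18 (5.38). Adm, Vegfa, Lcn2, Nppb, Metrnl and Tnfsf11 had ranges of 1.05 (Metrnl) to 2.01 (Adm) log2 units, as had Il6 (1.63) and Inhba (1.36). A range that reaches down to the floor has no firm lower end, since no detection calls were used. This holds for Il6, and for Bmp2, Slit2 and Inhbb, whose lowest means (4.59, 4.72 and 5.21) lay under the filter level of 5.3. Single arrays of Bmp2 lay between 4.45 and 5.19 in subclones 23 and 24, so its lowest rank is among such values too. All 15 genes named here passed the F-test, with the highest adjusted p being 1.02e-06 (Inhba).

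**Figure D3:**
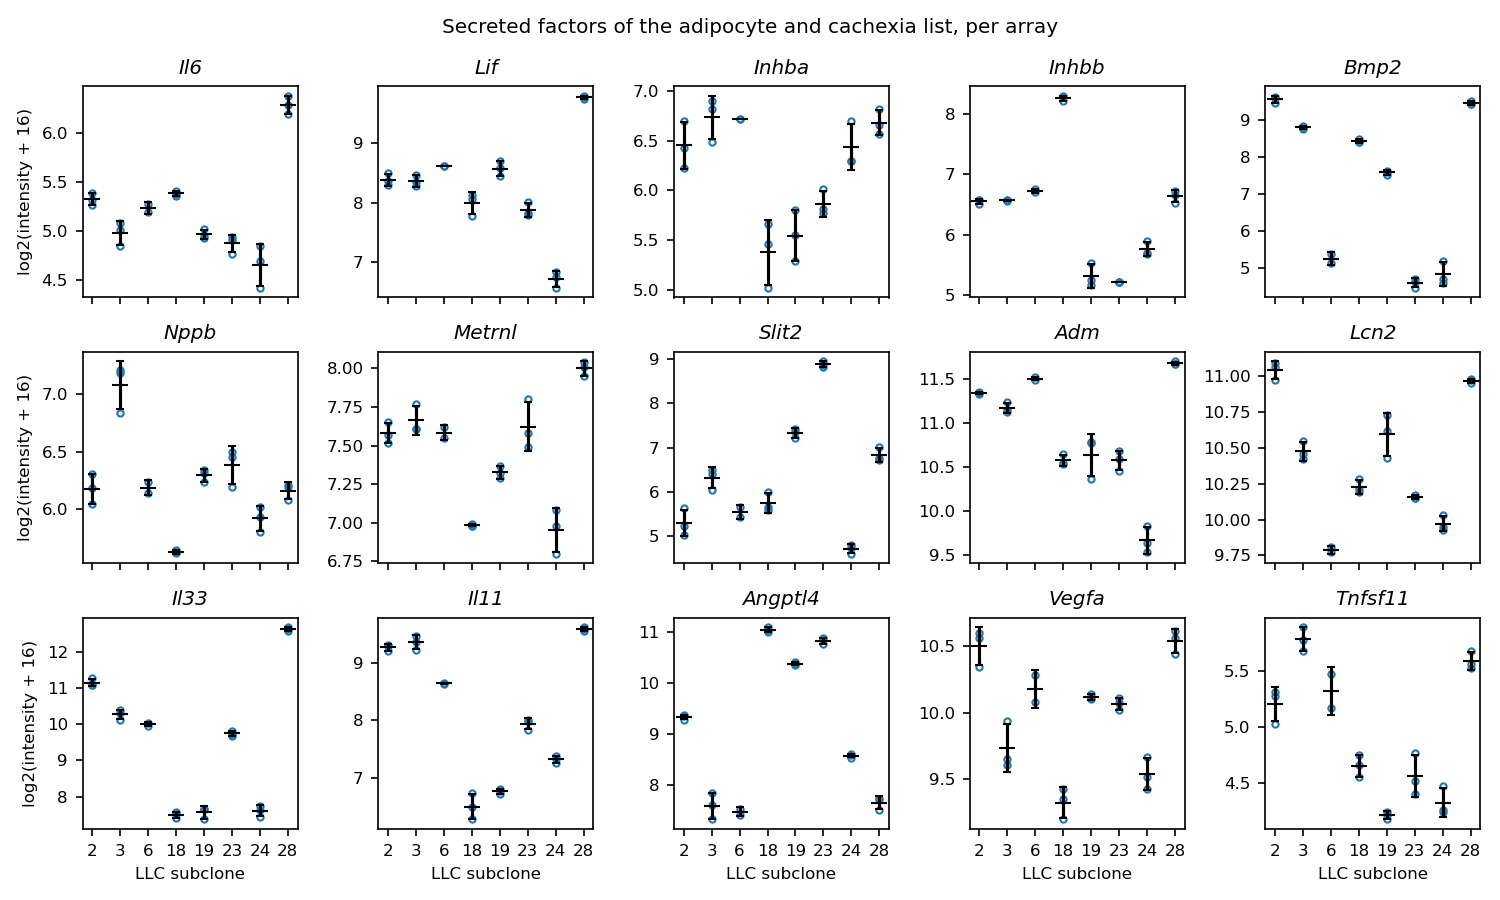
Log2(intensity + 16) of 15 secreted factors in each LLC subclone. Circles are single arrays, horizontal marks are means and bars are SD, and each panel has its own vertical scale. Il33 is at 12.62 in subclone 28 and at 7.5 in subclone 18.

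In subclone 2, 87 genes were higher and 114 lower than in the mean of the others, and 7 were private to it. Mmp12, the macrophage metalloelastase gene, was 16.9-fold higher (log2 difference 4.08 ± 0.095 SE, adjusted p = 1.02e-15). Lsp1 and Slfn2 were also privately higher, by 1.83 and 1.52 log2 units. Tbc1d4, a regulator of glucose transporter traffic, was 3.74-fold lower, and Stxbp6, Lmo1 and Cdca8, a part of the chromosomal passenger complex, were 2.25- to 3.60-fold lower. Of 44 proliferation genes, 43 were lower and 1 higher, and 44 passed when adjusted over the list alone, with a median of -0.75. Cdc20 (-1.27 ± 0.057), Cenpe (-1.16 ± 0.049) and Kif11 (-1.09 ± 0.044) showed the largest differences besides Cdca8. The camera adjusted p was 3.68e-31, but the adjusted p was 0.109 with an estimated correlation. Of 43 extracellular proteases and inhibitors, 23 were higher and 6 lower (31 passing adjusted over the list alone), among them Mmp13 (2.34 ± 0.061), Mmp3 (2.33 ± 0.038) and Timp3 (1.49 ± 0.086). That list had an adjusted p of 5.71e-05, and an adjusted p of 0.2 with an estimated correlation. Hypoxia and glycolysis genes were higher in 21 of 33 and lower in 1 (22 adjusted over the list alone), led by Ankrd37 (0.89 ± 0.073) and Egln3 (0.81 ± 0.056), with an adjusted p of 2.23e-08 and an adjusted p of 0.313 with an estimated correlation. Of 37 adipocyte and cachexia factors, 10 were higher and 3 lower (13 adjusted over the list alone), with Bmp2 at 2.57 ± 0.085. Its adjusted p was 0.0145, and its adjusted p was 0.0992 with an estimated correlation. Growth factors, with Pgf at 1.08 ± 0.11 and Bdnf at 0.80 ± 0.043 and 17 of 56 higher and 10 lower (27 adjusted over the list alone), had an adjusted p of 0.0355, and an adjusted p of 0.379 with an estimated correlation.

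In subclone 3, 96 genes were higher and 74 lower, and 8 were private to it. Afp, the fetal plasma protein alpha-fetoprotein, was 7.15-fold higher (2.84 ± 0.077, adjusted p = 8.74e-15), and Elovl7, Socs2 (a suppressor of cytokine signalling) and Npnt were 5.57-, 4.15- and 2.70-fold higher. Saa3, an acute-phase protein gene, was 5.66-fold lower (-2.50 ± 0.061, adjusted p = 2.62e-15), and Ptn, Slc45a4 and Ptpn13 were 3.66-, 3.20- and 3.11-fold lower. Of 31 genes of sterol and fatty acid synthesis, 25 were higher and 2 lower (29 adjusted over the list alone), with Idi1 at 1.12 ± 0.044, Acss2 at 1.09 ± 0.053 and Msmo1 at 0.94 ± 0.036. Camera gave an adjusted p of 1.38e-11, and an adjusted p of 0.17 with an estimated correlation. NRF2 targets, genes of the antioxidant response, were higher in 17 of 26 and lower in 4 (22 adjusted over the list alone), with Gsta2 at 1.24 ± 0.12 and Cbr3 at 1.18 ± 0.036. For this list, the adjusted p was 0.000104, and the adjusted p was 0.17 with an estimated correlation. Proliferation genes, with Tpx2 at 0.50 ± 0.048 and E2f8 at 0.45 ± 0.038, were higher in 22 of 44 and lower in 3 (25 adjusted over the list alone). Their camera adjusted p was 0.00109, and 0.658 with an estimated correlation. The mean level of this list was 9.87, 9.88, 9.87 and 9.89 in subclones 3, 6, 23 and 24. It was 9.1 in subclone 2, which lowers the mean of the others for each of these 4. Interferon-stimulated genes were lower in 16 of 40 and higher in 2 (18 adjusted over the list alone), with Gbp2 at -1.28 ± 0.077 and the transcription factor gene Irf1 at -0.96 ± 0.051. The list had an adjusted p of 0.0149, and an adjusted p of 0.191 with an estimated correlation. Of 50 collagens and matrix proteins, 23 were lower and 8 higher (31 adjusted over the list alone), with Col6a2 at -1.81 ± 0.054 and Col6a1 at -1.46 ± 0.048, and an adjusted p of 0.00787, or an adjusted p of 0.293 with an estimated correlation. Bgn (1.84 ± 0.071) and Efemp1 (1.46 ± 0.084) were higher by this measure because their low levels elsewhere, in subclones 18 and 19 and in 19 and 28, lower the mean of the others. Targets of TGF-beta and YAP, with Ankrd1 at -1.42 ± 0.084 and Amotl2 at -0.97 ± 0.056, were lower in 11 of 27 and higher in 4 (15 adjusted over the list alone; adjusted p = 0.0478, and adjusted p = 0.468 with an estimated correlation).

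Subclone 6 stood least apart, with 74 genes higher and 21 lower and 1 private gene. Among genes whose arrays all lay beyond those of the other subclones, Cthrc1 was 9.33-fold higher (3.22 ± 0.12), Crabp1 8.32-fold, Smarca1 5.64-fold, Glrb 4.07-fold, Stc1 3.27-fold and Tspan6 3.08-fold. Cthrc1, Crabp1, Stc1 and Tspan6 were also high in other subclones, and were low in subclone 19 and in 1 or 2 more, which lowers the mean of the others. Krt73 was 2.23-fold lower. Angpt1, a ligand of the endothelial Tie2 receptor, was 3.08-fold lower, but its level of 4.43 was close to those in subclones 19 (4.72) and 28 (4.70), against 6.27 or more elsewhere. Targets of p53 were lower in 16 of 26 and higher in 0 (17 adjusted over the list alone), with Btg2 at -0.82 ± 0.072, Pmaip1 at -0.74 ± 0.047 and Mdm2 at -0.63 ± 0.057. The adjusted p was 1.97e-13, and this call held with an estimated correlation (adjusted p = 0.0081). Genes of sterol and fatty acid synthesis were higher in 25 of 31 and lower in 0 (26 adjusted over the list alone), with Idi1 at 0.90 ± 0.053 and Cyp51 at 0.68 ± 0.052 and an adjusted p of 2.07e-17, or an adjusted p of 0.0992 with an estimated correlation. Hypoxia and glycolysis genes, with Ankrd37 at 0.91 ± 0.088 and Ero1a at 0.77 ± 0.075, were higher in 21 of 33 and lower in 1 (25 adjusted over the list alone; adjusted p = 3.45e-09, and adjusted p = 0.293 with an estimated correlation). Proliferation genes, with Cenpf at 0.52 ± 0.072 and Mcm3 at 0.43 ± 0.043, were higher in 19 of 44 and lower in 0 (28 adjusted over the list alone; adjusted p = 7.56e-06, and adjusted p = 0.532 with an estimated correlation). Proteases and inhibitors, with Mmp12 at 2.36 ± 0.11 and Plau at 1.18 ± 0.064, were higher in 13 of 43 and lower in 5 (21 adjusted over the list alone; adjusted p = 0.0223, and adjusted p = 0.468 with an estimated correlation). Cytokines and chemokines, with Cxcl5 at 0.93 ± 0.068 and Tslp at 0.80 ± 0.11, were higher in 14 of 44 and lower in 4 (22 adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.17 with an estimated correlation). The list of ribosomal proteins was called lower with 3 of 31 genes lower and 0 higher, Rps25 (-0.24 ± 0.036), Rpl12 (-0.24 ± 0.068) and Rps2 (-0.10 ± 0.035), and a median of -0.05 (2 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.682 with an estimated correlation). With all other arrays as one group, subclone 6 had 4 genes apart in place of 95.

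Subclone 18 stood furthest apart, with 156 genes higher, 325 lower and 125 private. The epithelial keratin gene Krt8 was 35.4-fold lower (-5.14 ± 0.045, adjusted p = 2.16e-22), at 5.70 ± 0.14 (SD, n = 3) against 10.32 or more in the others. The adhesion molecule gene Cadm1 was 33.4-fold lower, Trim44 31.5-fold, Sesn3 21.5-fold, Zfp518a 15.6-fold and Birc3, an inhibitor of apoptosis, 12.9-fold. Celf2, which encodes an RNA binding protein, was 20.1-fold higher (4.33 ± 0.087, adjusted p = 1.66e-17). Runx1t1, the leukaemia inhibitory factor receptor gene Lifr, the imprinted gene Ndn, Vgll3 and the PDGF receptor gene Pdgfrb were 11.1- to 15.1-fold higher. Hypoxia and glycolysis genes were lower in 29 of 33 and higher in 3 (33 adjusted over the list alone), with Ero1a at -1.60 ± 0.063, Egln3 at -1.37 ± 0.056 and the glucose transporter gene Slc2a3 at -1.32 ± 0.054. Camera gave an adjusted p of 2.18e-12, and an adjusted p of 0.2 with an estimated correlation. Targets of p53 were higher in 22 of 26 and lower in 0 (22 adjusted over the list alone), with Plk2 at 1.48 ± 0.046, Pmaip1 at 1.25 ± 0.039 and Btg2 at 0.99 ± 0.06. Their adjusted p was 2.59e-09, and the call held with an estimated correlation (adjusted p = 0.0215). Proliferation genes were higher in 37 of 44 and lower in 2 (40 adjusted over the list alone), with Ccne2 at 0.94 ± 0.054 and Tk1 at 0.69 ± 0.053 and an adjusted p of 1.2e-10, or an adjusted p of 0.349 with an estimated correlation. Proteases and inhibitors were lower in 23 of 43 and higher in 6 (30 adjusted over the list alone), with Ctsh at -2.84 ± 0.076 and Mmp9 at -2.27 ± 0.06, and an adjusted p of 4.09e-05, or an adjusted p of 0.195 with an estimated correlation. Genes of reticulum stress and the amino acid response were lower in 24 of 37 and higher in 5 (29 adjusted over the list alone), with the cystine transporter gene Slc7a11 at -1.48 ± 0.057 and Trib3 at -1.28 ± 0.063. For this list, the adjusted p was 7.33e-05, and the adjusted p was 0.158 with an estimated correlation. ERK pathway output was lower in 14 of 23 and higher in 6 (20 adjusted over the list alone), with Dusp5 at -1.47 ± 0.087 and Ereg at -1.25 ± 0.037, and an adjusted p of 0.00461, or an adjusted p of 0.516 with an estimated correlation. Dusp5 lies on chromosome 19, whose expressed genes had a median difference of -0.27 in this subclone. The list was not tested without that chromosome.

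In subclone 19, 161 genes were higher, 151 lower and 36 private. The stromelysin gene Mmp3 was 23.7-fold lower (-4.57 ± 0.038, adjusted p = 1.49e-22) and the collagenase gene Mmp13, of the same gene cluster, 10.3-fold lower. Basp1 was 22.2-fold lower, Oplah 15.4-fold, the selenium transport protein gene Selenop 11.1-fold and Fam20c 8.58-fold. Car9, a carbonic anhydrase gene induced by hypoxia, was 10.4-fold higher (3.37 ± 0.1, adjusted p = 1.78e-14), and Blnk and Serpinb7 7.98- and 6.21-fold higher. The guanylate binding protein genes Gbp8, Gbp7 and Gbp2 were 5.74-, 4.88- and 4.51-fold higher. Interferon-stimulated genes were higher in 18 of 40 and lower in 4 (23 adjusted over the list alone), with Gbp3 at 2.01 ± 0.077 and Parp14 at 0.79 ± 0.055, and an adjusted p of 0.0309, or an adjusted p of 0.234 with an estimated correlation. Gbp2 and Gbp3 lie on chromosome 3, whose expressed genes had a median difference of 0.23 in this subclone. The list was not tested without that chromosome. Of 50 collagens and matrix proteins, 16 were lower and 11 higher (31 adjusted over the list alone), with Bgn at -6.76 ± 0.071, Efemp1 at -5.93 ± 0.084 and Col6a2 at -2.55 ± 0.054. The list had a median of -0.05, an adjusted p of 0.0223 and an adjusted p of 0.368 with an estimated correlation. Mesenchymal genes were lower in 16 of 32 and higher in 5 (23 adjusted over the list alone), with Myl9 at -1.06 ± 0.073 and Cdh2 at -0.63 ± 0.055 and an adjusted p of 0.00787, or an adjusted p of 0.313 with an estimated correlation. Proteases and inhibitors, with Mmp12 at -2.64 ± 0.095 and Timp3 at -1.93 ± 0.086 beside Mmp3 and Mmp13, were lower in 21 of 43 and higher in 9 (30 adjusted over the list alone; adjusted p = 0.000996, and adjusted p = 0.293 with an estimated correlation). Genes of sterol and fatty acid synthesis were lower in 20 of 31 and higher in 4 (25 adjusted over the list alone), with Tm7sf2 at -1.05 ± 0.053 and Idi1 at -0.89 ± 0.044, an adjusted p of 1.94e-06 and an adjusted p of 0.313 with an estimated correlation. Genes of reticulum stress and the amino acid response were higher in 23 of 37 and lower in 6 (30 adjusted over the list alone), with Atf3 at 0.93 ± 0.043 and Dnajc3 at 0.62 ± 0.04 while Slc7a11 was lower (-0.93 ± 0.057), an adjusted p of 0.00106 and an adjusted p of 0.2 with an estimated correlation. Atf3 lies on chromosome 1, with a median difference of 0.27 in this subclone, and this list was not tested without it either. Markers of endothelium, fibroblasts and adipocytes were higher in 0 of 24 and lower in 7 (7 adjusted over the list alone), with the matrix proteoglycan genes Dcn at -2.26 ± 0.055 and Lum at -1.05 ± 0.072. The list had an adjusted p of 0.00787, and an adjusted p of 0.116 with an estimated correlation.

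In subclone 23, 101 genes were higher, 105 lower and 19 private. Dppa4 was 17.4-fold higher (4.12 ± 0.071, adjusted p = 6.6e-18), Slit2 7.52-fold, the fatty acid transporter gene Cd36 5.98-fold, Pla1a 3.50-fold, the lymphangiogenic factor gene Vegfd 3.24-fold and Bex2 3.12-fold. Tmem185b was 8.78-fold lower (-3.13 ± 0.06, adjusted p = 3.77e-17) and Tesc 6.19-fold. Igf2r, an imprinted gene for a receptor that clears IGF2, was 5.79-fold lower, at 8.66 ± 0.058 (SD, n = 3) against 10.82 or more elsewhere. The genes Tmem176a and Tmem176b were 4.96- and 3.26-fold lower and Rab7b 3.47-fold lower. Cytokines and chemokines were lower in 14 of 44 and higher in 5 (19 adjusted over the list alone), with Ccl5 at -2.54 ± 0.097 and the neutrophil attractant genes Cxcl5 and Cxcl2 at -1.44 ± 0.057 and -1.28 ± 0.043. Camera gave an adjusted p of 0.0223, and an adjusted p of 0.169 with an estimated correlation. Genes of sterol and fatty acid synthesis, with Hsd17b7 at -1.04 ± 0.057 and Sqle at -0.61 ± 0.036, were lower in 17 of 31 and higher in 2 (21 adjusted over the list alone; adjusted p = 1.85e-05, and adjusted p = 0.368 with an estimated correlation). NRF2 targets were lower in 13 of 26 and higher in 4 (17 adjusted over the list alone), with Gsta3 at -1.97 ± 0.12 and Slc7a11 at -0.98 ± 0.057 and an adjusted p of 0.0234, or an adjusted p of 0.389 with an estimated correlation. Proliferation genes, with Cdc20 at 0.57 ± 0.057 and Cenpe at 0.50 ± 0.049 but Mcm6 at -0.52 ± 0.033, were higher in 24 of 44 and lower in 5 (34 adjusted over the list alone). Their camera adjusted p was 0.00106, and 0.658 with an estimated correlation. The mean level of this list (9.87) was close to those of subclones 3, 6 and 24, and the low level of subclone 2 (9.1) lowers the mean of the others. Genes of oxidative phosphorylation were lower in 16 of 39 and higher in 7 (23 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.696 with an estimated correlation). The 4 largest of these differences, in Ndufb3 (-0.64 ± 0.028), Ndufs1 (-0.63 ± 0.031), Sdhc (-0.58 ± 0.027) and Ndufa10 (-0.46 ± 0.031), lay in genes of chromosome 1. The 720 expressed genes of that chromosome, which also carries Tmem185b and Rab7b, had a median difference of -0.35 in this subclone. Gsta3 lies there as well. Without their members on chromosome 1, oxidative phosphorylation (median -0.03 over 34 genes against -0.04 over all 39, adjusted p = 0.497) and NRF2 targets (median -0.08 over 24 genes against -0.16 over all 26, adjusted p = 0.11) were no longer called. Cytokines, proliferation and sterol synthesis still were, but with an adjusted p of 0.149, 0.53 and 0.386 with an estimated correlation.

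In subclone 24, 65 genes were higher, 125 lower and 12 private. Adipocyte and cachexia factors were lower in 14 of 37 and higher in 0 (14 adjusted over the list alone), with Bmp2 at -2.83 ± 0.085, Il33 at -2.22 ± 0.069, Slit2 at -1.85 ± 0.11 and Lif at -1.79 ± 0.071. The adjusted p was 0.000501, and the call held with an estimated correlation (adjusted p = 0.0215). The median over the 37 genes was -0.05 and the mean -0.4, so strongly lower members weighed most. Of these, Bmp2 (single arrays 4.58 to 5.19) and Slit2 had means under the level of the filter on low values (5.3) in this subclone. The sizes of their differences are therefore uncertain. Lif and Tmem45a were private to this subclone on the low side (3.47- and 7.35-fold lower), as were Dock4 (6.82-fold), Tram1l1 (5.90-fold) and Arhgap29 (3.16-fold). Itih5 was 7.85-fold higher (2.97 ± 0.056, adjusted p = 5.39e-17), Tesc 6.33-fold, the nucleotide sugar receptor gene P2ry14 3.51-fold, Zkscan16 3.10-fold and Ecpas 2.42-fold. Hypoxia and glycolysis genes were lower in 27 of 33 and higher in 1 (30 adjusted over the list alone), with Adm at -1.40 ± 0.07 and Car9 at -1.15 ± 0.1. For this list, the adjusted p was 4.28e-12, and the adjusted p was 0.201 with an estimated correlation. Targets of p53 were lower in 19 of 26 and higher in 2 (23 adjusted over the list alone), with Ephx1 at -0.74 ± 0.037 and Mdm2 at -0.61 ± 0.048, while the death receptor gene Fas was higher (0.83 ± 0.055). The adjusted p was 1.12e-07, and the call held with an estimated correlation (adjusted p = 0.0408). Mdm2 lies on chromosome 10, whose expressed genes had a median difference of -0.24 in this subclone, and the list was not tested without that chromosome. NRF2 targets were lower in 19 of 26 and higher in 2 (21 adjusted over the list alone), with Gsta3 at -1.73 ± 0.12, Cbr3 at -1.35 ± 0.036 and Hmox1 at -1.12 ± 0.16. The list had an adjusted p of 9.12e-08, and an adjusted p of 0.0752 with an estimated correlation. Cbr3 lies on chromosome 16, with a median difference of -0.23 in this subclone, and the list was not tested without it either. ERK pathway output was lower in 15 of 23 and higher in 2 (18 adjusted over the list alone), with Hbegf at -0.99 ± 0.064 and Ier3 at -0.84 ± 0.052, an adjusted p of 7.56e-06 and an adjusted p of 0.293 with an estimated correlation. Proliferation genes, with Mcm6 at 0.42 ± 0.033 and Mcm5 at 0.39 ± 0.04, were higher in 29 of 44 and lower in 2 (32 adjusted over the list alone). Their camera adjusted p was 2.07e-07, and 0.475 with an estimated correlation. The mean level of this list (9.89) was close to those of subclones 3, 6 and 23, and the low level of subclone 2 (9.1) lowers the mean of the others. Interferon-stimulated genes, with Ifit1 at 0.89 ± 0.15 and Rsad2 at 0.73 ± 0.072 but Isg20 at -0.80 ± 0.043, were higher in 18 of 40 and lower in 5 (24 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.17 with an estimated correlation). Genes of sterol and fatty acid synthesis, with Nsdhl at 0.31 ± 0.056 and Acly at 0.29 ± 0.039 but Lss at -0.45 ± 0.064, were higher in 14 of 31 and lower in 2 (17 adjusted over the list alone; adjusted p = 0.00164, and adjusted p = 0.516 with an estimated correlation). Genes of oxidative phosphorylation, with Sdha at 0.39 ± 0.032 and Ndufa5 at 0.28 ± 0.037 but Ndufs7 at -0.38 ± 0.049, were higher in 15 of 39 and lower in 5 (22 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.696 with an estimated correlation).

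In subclone 28, 177 genes were higher, 63 lower and 29 private. Zfp503 was 26.2-fold higher (4.71 ± 0.075, adjusted p = 3.79e-18), the acyl-CoA thioesterase gene Acot1 15.9-fold, Il33 11.4-fold, Myo1d 11.2-fold, Tmem45a 7.21-fold and Plac8 6.48-fold. Sema3c was 6.21-fold lower (-2.64 ± 0.048, adjusted p = 2.63e-17), the heparanase gene Hpse 5.33-fold, Lrrc17 4.86-fold, Arap2 4.27-fold, Foxred2 4.08-fold and Tubb2b 3.39-fold. Adipocyte and cachexia factors were higher in 14 of 37 and lower in 3 (17 adjusted over the list alone), with Bmp2 at 2.44 ± 0.085 and Lif at 1.69 ± 0.071, while Angptl4 was lower (-1.67 ± 0.069). Camera gave an adjusted p of 0.0234, and an adjusted p of 0.116 with an estimated correlation. ERK pathway output was higher in 17 of 23 and lower in 2 (20 adjusted over the list alone), with Hbegf at 1.36 ± 0.064, Dusp5 at 1.30 ± 0.087 and Ereg at 1.20 ± 0.037. For this list, the adjusted p was 3.45e-09, and the adjusted p was 0.17 with an estimated correlation. Proteases and inhibitors were higher in 23 of 43 and lower in 7 (31 adjusted over the list alone), with Mmp3 at 2.09 ± 0.038 and Mmp9 at 1.96 ± 0.06 and an adjusted p of 1.52e-05, or an adjusted p of 0.17 with an estimated correlation. NRF2 targets were higher in 15 of 26 and lower in 3 (19 adjusted over the list alone), with Gsta3 at 2.21 ± 0.12 and Slc7a11 at 1.77 ± 0.057, and an adjusted p of 2.07e-05, or an adjusted p of 0.143 with an estimated correlation. Hypoxia and glycolysis genes, with Ero1a at 1.17 ± 0.063 and Adm at 0.90 ± 0.07, were higher in 23 of 33 and lower in 0 (25 adjusted over the list alone; adjusted p = 3.11e-09, and adjusted p = 0.293 with an estimated correlation). Genes of sterol and fatty acid synthesis were lower in 19 of 31 and higher in 2 (24 adjusted over the list alone), with Idi1 at -0.98 ± 0.044 and Msmo1 at -0.86 ± 0.036, an adjusted p of 5.58e-08 and an adjusted p of 0.248 with an estimated correlation. Proliferation genes were lower in 25 of 44 and higher in 5 (30 adjusted over the list alone), with Mcm5 at -0.93 ± 0.04 and Ccne2 at -0.82 ± 0.054, an adjusted p of 3.33e-05 and an adjusted p of 0.568 with an estimated correlation. Oxidative phosphorylation, with Ndufa5 at -0.47 ± 0.037 and Sdha at -0.34 ± 0.032, was lower in 19 of 39 genes and higher in 4 (25 adjusted over the list alone; adjusted p = 0.00596, and adjusted p = 0.658 with an estimated correlation). Antigen presentation genes were lower in 5 of 14 and higher in 1 (7 adjusted over the list alone), with Erap1 at -1.53 ± 0.072 and Psmb10 at -1.15 ± 0.051, an adjusted p of 0.0418 and an adjusted p of 0.435 with an estimated correlation. Msmo1, Mcm5 and Psmb10 lie on chromosome 8, whose expressed genes had a median difference of -0.25 in this subclone. Their lists were not tested without that chromosome.

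**Figure D4:**
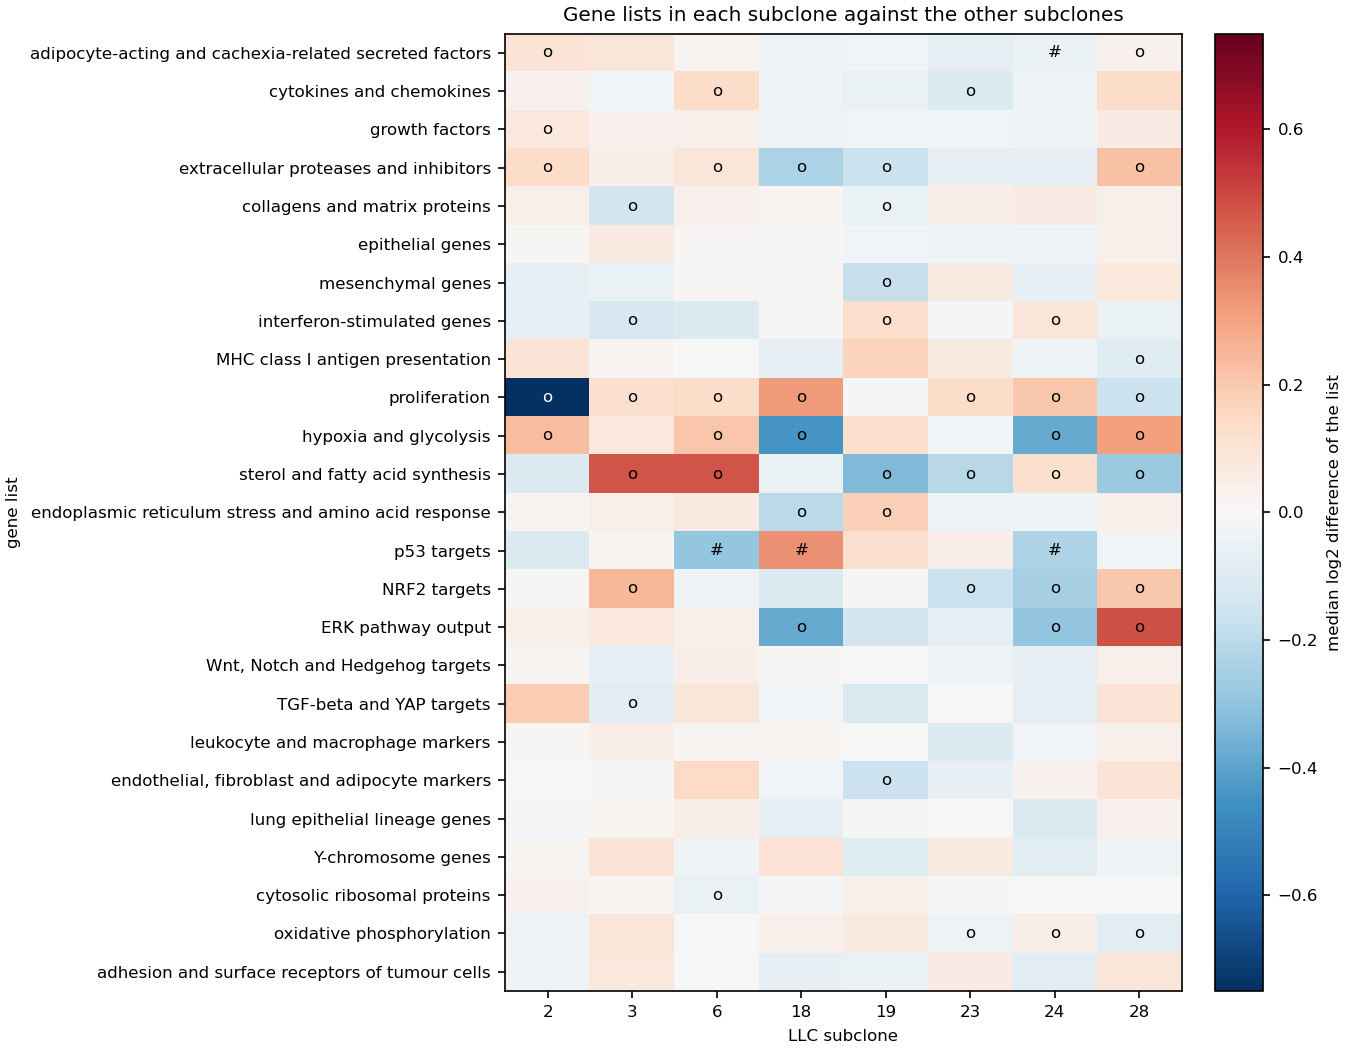
Median log2 difference of each of 25 gene lists in each LLC subclone against the mean of the other subclones, as colour. A circle marks a camera call at the preset correlation and a hash a call that also held with an estimated correlation, of which there were 4: p53 targets in subclones 6, 18 and 24, and the adipocyte and cachexia factors in subclone 24.

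Over all 200 combinations of list and subclone, 54 were called, 26 higher and 28 lower, and 4 held with an estimated correlation. All arrays of a subclone lay beyond all others in 790 to 2049 of 18194 genes with 3 arrays and in 351 with 2. Were all arrays interchangeable, this would arise in 0.113% of genes with 3 arrays and in 0.791% with 2. Replicates lay close together and most genes differed between subclones, so these shares are too low as a chance level for a given subclone.

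Genes for extracellular proteins were over-represented among the 454 genes with a range over 4-fold. Of 43 proteases and inhibitors, 13 were among them (30.2%, adjusted p = 5.67e-10), as were 11 of 50 collagens and matrix proteins (22%, adjusted p = 2.68e-07), 12 of 56 growth factors (21.4%, adjusted p = 1.3e-07) and 8 of 44 cytokines and chemokines (18.2%, adjusted p = 4.74e-05). Targets of TGF-beta and YAP (8 of 27, adjusted p = 1.29e-06) and ERK pathway output (4 of 23, adjusted p = 0.0083) were over-represented too. The lists share members, such as Lif, Il33, Bmp2 and Inhbb, so these tests are not independent. With low genes filtered out, 9 lists were enriched in place of 7. Among genes over 2-fold, 16 of the 25 lists were, so enrichment was not particular to extracellular proteins there. All 44 proliferation genes, 33 of 33 hypoxia and glycolysis genes, and 39 of 39 oxidative phosphorylation genes passed the F-test, with 0, 3 and 0 of them over 4-fold. Over 2-fold, however, were 25 of 44 proliferation genes (odds ratio 9.14, adjusted p = 1.05e-10) and 19 of 33 hypoxia and glycolysis genes (odds ratio 9.41, adjusted p = 1.48e-08), but 0 of 39 oxidative phosphorylation genes (adjusted p = 0.0116 for too few). Epithelial genes passed the F-test in 16 of 38, lung epithelial genes in 11 of 26, targets of Wnt, Notch and Hedgehog in 13 of 26 and surface receptors of tumour cells in 33 of 41 (the same counts adjusted over each list alone). Those 4 lists were called by camera in 0 subclones, whereas fry's directional test passed for each of them in 4 to 7 of the 8, as for epithelial genes in subclone 18 (adjusted p = 2.49e-11). Among markers of other cell types, 6 of 25 leukocyte markers passed the F-test (5 adjusted over the list alone), with no camera call in any subclone, though fry passed in 5 of 8, as in subclone 19 (adjusted p = 1.05e-08). Endothelial, fibroblast and adipocyte markers passed in 10 of 24, with a camera call in subclone 19 alone, which was lost with an estimated correlation (adjusted p = 0.116). Fry passed for this list in all 8 subclones, with the highest adjusted p being 0.0273 (subclone 23). Of 6 Y-chromosome genes measured, 1 passed (Eif2s3y, between 4.61 and 5.31, named after its values were seen), and camera did not call the list.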

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

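The settings planned for the gene counts were applied to private genes, replicate distance and list results as well, a choice made after seeing the data. The 326 values of named genes were refitted under 9 processing alternatives, but genes removed by the filter on low values had no refit there. Of 2919 refits, 2913 kept their direction and side of the adjusted p threshold of 0.05, 6 lost significance and 0 reversed. These 6 were Rps2 in subclone 6 under 5 alternatives and Tpx2 in subclone 3 under the mean of its probe sets. With single arrays left out, 7478 of 7498 refits kept both, and 20 lost significance. The named genes were chosen from these same data, mostly for large differences, so few refits could change side. The limit of 1 log2 unit and the criterion for private genes were not part of this check. Quantile normalization and median centring left each count of genes within 1.5 times, with array medians shifted by -0.05 to 0.07 log2 units. The replicate numbers did not pair the arrays: 77 same-numbered pairs had a mean correlation of deviations of -0.003, 8 of them over 0.1, and 5 of 23 arrays correlated best with their own number. With the replicate block, 11153 genes passed the F-test, 454 had a range over 4-fold, and 201, 170, 93, 480, 311, 205, 190 and 239 were apart in subclones 2, 3, 6, 18, 19, 23, 24 and 28.

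The size of the pseudocount sets how far low genes count. With a pseudocount of 1, 789 genes had a range over 4-fold, and 363, 342, 246, 730, 552, 388, 350 and 400 were apart in subclones 2, 3, 6, 18, 19, 23, 24 and 28. Private genes numbered 368, the median pair differed by 739.5 genes, 11 lists were enriched and the distance ratio was 0.718. With a pseudocount of 64, these were 236 genes over 4-fold, 84, 78, 39, 296, 156, 103, 86 and 134 genes apart, 114 private genes, 253 genes in the median pair and a ratio of 0.334. A filter on low values left 12371 genes and a ratio of 0.336. The mean of a gene's probe sets gave 133 genes apart in subclone 2, 152 private genes and 11 enriched lists; the cause was not tested.

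Stricter definitions lowered the counts by construction. At 2 log2 units, 16, 17, 13, 114, 66, 29, 23 and 34 genes were apart in the same order of subclones, and with limma's treat 83, 89, 38, 319, 170, 110, 105 and 124. With all other arrays as one group, differences among them enter the spread, and 77, 53, 4, 90, 69 and 119 genes were apart in subclones 2, 3, 6, 23, 24 and 28. A gap of 0.5 gave 704 private genes and a gap of 2 gave 38. List calls numbered 4 with an estimated correlation and 159 with fry, and 16 lists were enriched among genes over 2-fold.

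Leaving out each array in turn gave 11043 to 11397 genes past the F-test, 452 to 459 over 4-fold, 233 to 241 private genes, 448.5 to 464 genes in the median pair, 50 to 60 list calls, 6 to 9 enriched lists and a ratio of 0.469 to 0.486. Genes apart ranged from 191 to 216 in subclone 2, 165 to 181 in 3, 93 to 106 in 6, 478 to 494 in 18, 309 to 319 in 19, 202 to 213 in 23, 187 to 203 in 24 and 236 to 243 in 28. Where subclone 6 kept 1 array, that array was assumed to vary like those of the other groups.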

Other observations

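The genes that were low in both subclones 18 and 19 clustered on the X chromosome. Taking genes whose mean in each of these subclones lay at least 2 log2 units below the lowest of the other 6 gave 15 genes, a larger number than for any other pair of subclones (at most 1). Of them, 13 lie on chromosome X: Bgn, Armcx2, Col4a5, Tmem47, Tspan6, Prrg1, Maged2, Armcx3, Lrch2, Rnf128, Lonrf3, Nxt2 and Magee1. The other 2 were Tspyl3 and Tgfb1i1, and all these genes were named after their values were seen. The median difference of the X genes was -3.64. Over all expressed genes of the X chromosome, the median difference was -0.04 in subclone 18 and 0.03 in subclone 19.

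The tests on the placement of these genes, on a stretch of X, on Xist, on the 4 parts of chromosome 1 and on the 8 subclone means of the list pair were chosen after the result was seen. Chance placement would put 3.42% of the genes on X and not 86.7% (Fisher's exact test, one-sided, p = 7.68e-18). A single failing probe set is argued against by 13 other probe sets of 11 of the genes, with a median difference of -3.44. Loss of an unbroken stretch is argued against by the 227 other expressed X genes between them, the genes of the set being left out. By the mean of subclones 18 and 19, 97.4% of these lay less than 1 log2 unit below the other 6 subclones. High Xist RNA alone is argued against by subclone 28, where Xist was as high. Chosen by the same gap without regard to subclone 28, 14 X genes had a median difference there of -0.02 from the remaining 5 subclones, and 1 of them, Ptchd1, was low (-2.57). Silencing of these genes on a retained X, or several small losses, may underlie the pattern, but neither was tested.

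Expressed genes of some chromosomes were shifted together. Among 160 combinations of chromosome and subclone, 9 had an absolute median difference of at least 0.2 over expressed genes, the largest being -0.35 for chromosome 1 in subclone 23. Others were -0.27 for chromosome 19 in subclone 18, 0.27 for chromosome 1 in subclone 19, -0.25 for chromosome 8 in subclone 28 and -0.24 for chromosome 10 in subclone 24. For chromosome 1 in subclone 23, 0 of 10000 random draws of as many genes reached the shift in any subclone, with a largest draw of 0.08. Scaling is argued against by a shift of -0.37 after quantile normalization, and a few strong genes by 88.1% of the 720 genes lying below the others. A lower copy number of the whole chromosome is a candidate explanation: 4 parts with equal numbers of genes had medians of -0.40, -0.30, -0.35 and -0.32, so the one nearest to 0 was at -0.3. DNA was not analysed here, and this stays a hypothesis. Of the 5 list calls in subclone 23, those for oxidative phosphorylation and NRF2 targets were lost without the members on chromosome 1 (camera in limma, adjusted p = 0.497 and adjusted p = 0.11), although the median of the former moved only from -0.04 to -0.03. The other 3 were kept, and matrix proteins (adjusted p = 0.0359) and mesenchymal genes (adjusted p = 0.0356) gained a call. None of these 5 held with an estimated correlation (adjusted p = 0.149 for cytokines, 0.53 for proliferation, 0.386 for sterol synthesis and 0.312 for each gained list).

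Proliferation genes and hypoxia with glycolysis genes tended to oppose each other. Across the 8 subclones, the list means had r = -0.6 (exact permutation p = 0.102) and rho = -0.71 (exact permutation p = 0.0576), and r = -0.73 without subclones 2 and 28, so neither p passed 0.05 for the 1 relation tested. Residuals around the subclone means had r = -0.03 over 23 arrays (permutation p = 0.422, one-sided) and -0.2 to 0.28 without each subclone in turn. The list means varied little between arrays of a subclone (SD 0 to 0.09), so the correlation of these residuals decides little. Subclone means ran from 9.1 to 10.03 for proliferation and from 9.84 to 10.71 for hypoxia and glycolysis. Provided that each array stands for its own dish, so small a spread argues against states of single dishes as the source of these differences between subclones. Growth rate or density common to all dishes of a subclone may play a part and cannot be told apart from the subclone itself.

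Random assignment of the arrays to groups of the same sizes was drawn until, with the real one, there were 100 assignments. For each of these results, 1 of 100, the real one, gave a value as large. Random assignments separate replicate arrays, so differences between subclones enter the spread and the counts fall. The comparison therefore shows that arrays group by subclone, and tests no single subclone. The real 11243 genes past the F-test compared with at most 3 in the others, and 454 genes over 4-fold with at most 0. Genes apart numbered 201, 170, 95, 481, 312, 206, 190 and 240 against at most 1, 0, 28, 1, 49, 40, 0 and 19 in subclones 2, 3, 6, 18, 19, 23, 24 and 28. Private genes were 237 against 20, genes in the median pair 454.5 against 0, list calls 54 against 43 and enriched lists 7 against 0. A random assignment thus gave up to 43 list calls, so their number alone says little about the subclones.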
